A study of Mus musculus with 15 samples.

How the data were processed

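RNA sequencing measured gene expression in sorted mononuclear phagocytes of mouse kidneys, in 15 libraries that fall into 5 groups of 3. Per the labels, RNA was isolated with a miRNeasy Micro kit, libraries were made with the Agilent SureSelect Stranded mRNA kit, and a NextSeq500 instrument was used; the strand setting of the read counting is not stated. Per the submitters' processing notes, the reads passed through bcl2fastq 1.8.4, Trim Galore 0.4.0, TopHat2 2.0.12, Bowtie2 2.2.3, Cufflinks 2.2.1 and Cuffdiff. The notes name the human genome build hg19, whereas all 48488 genes of the deposited table carry mouse Ensembl identifiers. Of these, 48349 are in GENCODE mouse release 21, and 97.4% of those have the same start and end there, so coordinates are given as the table has them.

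The per-library values that the authors deposited are a signal, namely gene counts divided by 1 size factor per library (DESeq2-normalized counts). Every value in all 15 libraries was a whole multiple of its library's smallest step within a tolerance of 0.001, so whole reads were recovered and summed to give each library's depth. The authors also deposited a mean signal per gene, a log2 fold change and a p-value with its adjusted p-value, for a single comparison that the file does not name. These log2 fold changes tracked those of postnatal day 7 against uninjured macrophages (r = 0.998 across 13203 genes) more closely than those of any other pair of groups. The authors' mean signal equals the plain mean of the 15 libraries within 1e-06 in all but 4 genes, Prg4, Alox15, Saa3 and Cxcl13.

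The deposited unit is not counts, so the plan's alternative for normalized values was used: limma (trend and robust options) on log2 of the normalized count plus 1. Genes with a mean normalized count of at least 1 were tested (24911 of the 33054 with any read). All 15 libraries entered a single fit with 1 mean per group and no block, which gives the groups a shared estimate of spread, and 6 comparisons were drawn from it. The tests are two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Log2 fold changes are on this log2(value + 1) scale, which understates changes of genes with low counts. Against a group with no reads, a fold is given as a lower bound computed from a floor of 3 reads over the group; against a group with 1 to 3 reads, a ratio with its counting interval is given. Such bounds and intervals cover counting error only.

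Gene lists were fixed before the data were examined, as were the comparisons, the main tests and the rule for naming genes. There are 24 lists: MHC class II presentation, Wnt pathway, cell cycle, resident macrophage core, LYVE1 TIMD4 FOLR2 macrophage, infiltrating monocyte, inflammatory cytokines, type I interferon response, alternative activation and repair, efferocytosis, complement, glycolysis and hypoxia, oxidative phosphorylation, fetal growth genes, immediate early and heat shock, and markers of 9 other cell types (nephron epithelium, nephron progenitor, endothelium, stroma, T and NK cell, B cell, neutrophil, dendritic cell, erythroid). The Wnt list was chosen in the knowledge that a publication on these samples treats that pathway, so its count is not independent evidence of its direction; the fetal growth, LYVE1 and cell cycle lists were chosen with the postnatal samples in mind. Each list was tested with camera in limma at a preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the 24 lists. Camera compares a list with all other genes, whereas fry does not.

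The genes named in each comparison follow a fixed rule. It takes the 10 largest rises and 10 largest falls among genes past the threshold with at least 10 CPM (reads scaled to a common library total) in the higher group and no overlap between the libraries of the groups, leaving out symbols of predicted, RIKEN, mitochondrial, immunoglobulin and T cell receptor segment genes. For injured MHCII-negative against uninjured macrophages it takes 5 and 5. It adds up to 2 members per list and direction with the smallest adjusted p, and 9 genes that check the labels (H2-Ab1, H2-Aa, Cd74, Ciita, Ly6c2, Ccr2, Adgre1, Cx3cr1 and Itgam). The text leaves out part of these.

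Depth ranged from 13482981 to 34295930 reads per library, with 22386 to 27863 genes detected. The gene Gm26917 took 7.53% to 12.6% of the reads of a library. No pair of replicates agreed within sampling noise (chi-square per gene from 3.31 to 36.7 for genes with at least 20 reads in the pair). The method was tested on simulated data drawn from the real genes' means, dispersions and library sizes, with known changes in 194 to 199 of the tested genes per comparison. It recovered 12.3% to 21.5% of genes changed 1.5-fold, 37.9% to 59.1% of those changed 2-fold and 50.0% to 76.6% of those changed 4-fold, while 0% to 12.6% of the calls were false. The highest of these false shares was above the threshold of 0.05. In the real comparisons 9.17% to 60.2% of tested genes passed, far more than were changed here, so the simulated rates need not hold there. The list test found the changed list in all 6 comparisons.

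Alternatives planned before the data were examined were a pseudocount of 0.1 or 5, other filters on low values, only the 6 libraries of both groups, a minimum fold, edgeR with RLE or upper quartile factors, DESeq2, limma-voom, each library left out in turn, and a replicate block for the comparison in which the label numbers match. Further alternatives were added after the data were seen: TMM factors, the marker means of other kidney cells as covariates, and fits without doubted libraries or with matched libraries as a block. For the list test, the RLE alternative is the deposited scaling itself and was not run separately. Software was R 4.3.3 with limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0 and the package data.table at version 1.17.8. The deposited sheets that repeat the same genes past the authors' thresholds were left out, since they hold no further values.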

Results

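Gene expression was measured by RNA sequencing in 15 libraries of mononuclear phagocytes sorted from mouse kidneys, 3 in each of 5 groups. Kidney resident macrophages positive for MHC class II came from uninjured adult kidneys (replicates 95, 96 and 98) and from kidneys after acute kidney injury by ischemia and reperfusion (replicates 4, 5 and 6). Resident macrophages negative for MHC class II came from injured kidneys and from pups at postnatal day 7 (replicates 1, 2 and 3 of each), and MHC class II positive infiltrative mononuclear phagocytes came from injured kidneys (replicates 69, 70 and 73). The adults were 10-week-old males. The labels do not give the time after injury, nor say whether the libraries of a group came from separate animals, so the p-values measure only the spread between these libraries. In the same order of replicates, totals were 15311669, 14674208 and 34295930 reads in uninjured macrophages and 20919924, 13482981 and 29292355 in injured MHCII-positive ones. They were 15770875, 15772723 and 21547187 in injured MHCII-negative macrophages, 20843771, 15747572 and 22356640 at day 7, and 19788225, 20530650 and 17373168 in infiltrative phagocytes.

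The groups separated along the first principal components, which held 48.3%, 31.2% and 13.1% of the variance of the 500 most variable genes. The closest groups were the injured MHCII-positive and MHCII-negative resident macrophages, at a mean distance of 35.0. Injured MHCII-negative macrophages lay 77.1 from day 7 macrophages and 86.6 from uninjured ones, a ratio of 0.892 (SD 0.0456, n = 3). Injured MHCII-positive macrophages lay 78.3 from day 7 and 71.3 from uninjured ones, so the injured groups differed mainly in their distance from uninjured macrophages. Distances within groups averaged 17.3 to 28.6. The titles of the libraries come in 2 styles, 1 for infiltrative phagocytes and uninjured macrophages and another for the rest. Mitochondrial ribosomal RNA took 1.89% to 2.61% of reads in the first and 5.86% to 10.2% in the second. If the styles mark batches, batch and group cannot be told apart in the comparisons that cross them, which are all those with uninjured macrophages or infiltrative phagocytes; no batch holds both groups.

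**Figure D1:**
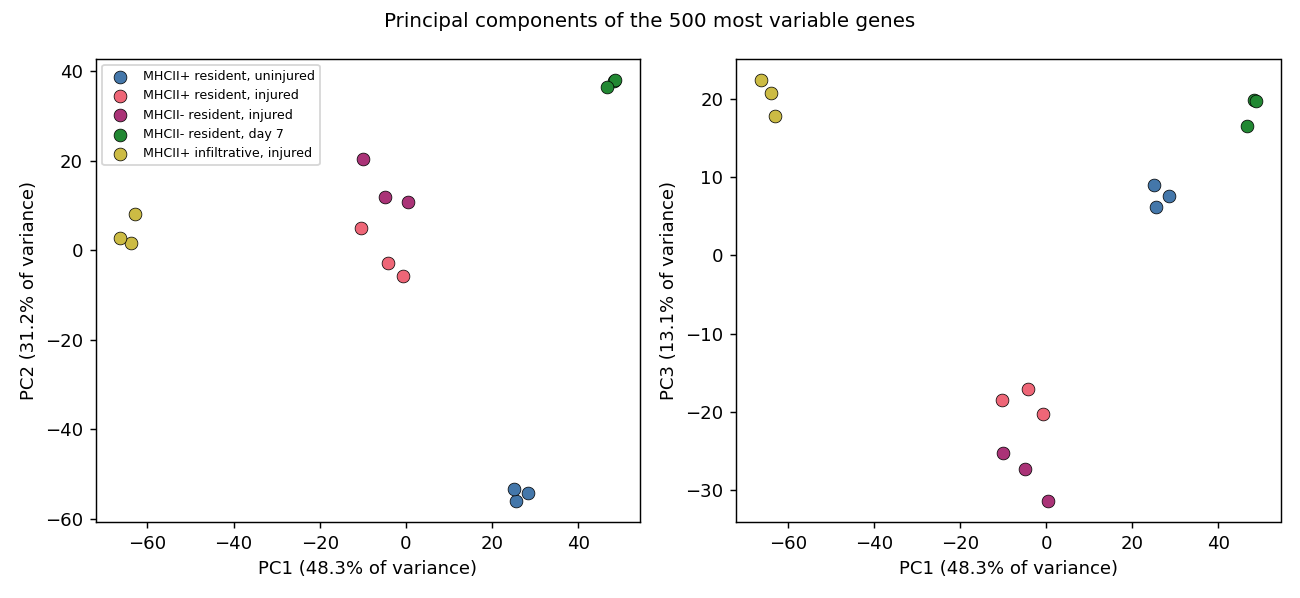
Principal components of log2 normalized counts of the 500 most variable genes, with the first component against the second and against the third; each point is 1 of 15 libraries, coloured by group. The libraries of each group lie together, and injured MHCII-negative libraries lie next to injured MHCII-positive ones.

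The first comparison asked how MHCII-positive resident macrophages differ between injured and uninjured kidneys. Fn1, which encodes fibronectin, rose from 86.8 ± 10.1 to 15943 ± 4185 normalized counts (SD, n = 3 per group; log2 fold change 7.48, SE 0.19, adjusted p = 5.79e-11). Gpnmb, a glycoprotein of lipid-laden macrophages, rose by 7.47 (SE 0.49, adjusted p = 1.39e-07), and Il1rn, the interleukin-1 receptor antagonist, rose by 6.79 (SE 0.21, adjusted p = 3.17e-11). Spp1, which encodes osteopontin, rose from 143 ± 51.6 to 11852 ± 7293, and Thbs1, which encodes thrombospondin, from 387 ± 24.6 to 22648 ± 6030. Slc7a11, the cystine transporter, rose by 6.83 and the pattern receptor genes Clec4e and Clec4d by 6.93 and 6.66. Among the falls were the collagenase gene Mmp13, from 11180 ± 712 to 1773 ± 190 (log2 fold change -2.66, SE 0.24, adjusted p = 3.35e-06), and the adrenergic receptor gene Adrb1 (-3.02, SE 0.24, adjusted p = 5.57e-08). The core macrophage gene Adgre1 stood at 30567 ± 1686 against 33507 ± 1202 (adjusted p = 0.192) and the chemokine receptor gene Cx3cr1 at 17088 ± 3081 against 18746 ± 3295 (adjusted p = 0.618).

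Cell division and macrophage subset genes moved together. Of 42 cell cycle genes, 39 rose, none fell and 3 did not pass (40 rose adjusted over the list alone, adjusted p = 5.96e-18, and 0.0645 with an estimated correlation); Top2a, the DNA topoisomerase of dividing cells, rose from 319 ± 49.2 to 1418 ± 129. In the LYVE1 TIMD4 FOLR2 list, which marks a subset of tissue macrophages, 16 of 18 genes rose (17 adjusted over the list alone, adjusted p = 1.46e-08, and 0.027 with an estimated correlation). Its mannose receptor gene Mrc1 rose from 15963 ± 1686 to 39344 ± 1525 (log2 fold change 1.31, SE 0.08, adjusted p = 2.29e-09). Alternative activation and repair held the same way, with 17 rises and 4 falls of 22 (17 and 4 adjusted over the list alone, adjusted p = 3.04e-06, and 0.027 with an estimated correlation). Its falls included the lectin gene Mgl2 (-0.73) and the growth factor gene Pdgfb (-1.31).

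Inflammatory and metabolic lists also rose by the main list test. Of inflammatory cytokine genes 19 of 24 rose (20 rose and 1 fell adjusted over the list alone, adjusted p = 1.28e-08, and 0.134 with an estimated correlation), with the monocyte attractants Ccl7 at 3.87 and Ccl2 at 2.56. Of infiltrating monocyte genes 14 of 20 rose and 1 fell (15 and 1 adjusted over the list alone, adjusted p = 1.69e-06, and 0.141 with an estimated correlation); Ccr2, the monocyte chemokine receptor, rose by 1.59, while Ly6c2 stood at 20.2 ± 10.2 against 11.9 ± 2.17 (adjusted p = 0.361). Glycolysis and hypoxia had 19 rises of 22 (19 adjusted over the list alone, adjusted p = 1.33e-07, and 0.141 with an estimated correlation) and oxidative phosphorylation 22 of 26 (22 adjusted over the list alone, adjusted p = 2.75e-09, and 0.208 with an estimated correlation); examples are Pgk1 at 1.43 and Ndufa2 at 1.73. Complement had 9 rises and 2 falls of 16 (9 and 2 adjusted over the list alone, adjusted p = 0.0224, and 0.216 with an estimated correlation), with properdin gene Cfp at 3.86 and Itgax at -0.90. Efferocytosis, the uptake of dying cells, had 9 rises and 4 falls of 19 (11 and 4 adjusted over the list alone, adjusted p = 0.0099, and 0.0645 with an estimated correlation), with the lipid receptor gene Trem2 at 2.87 and the receptor gene Axl at -0.46 (adjusted p = 0.227 with marker means of other kidney cells as covariates). Immediate early and heat shock genes had 14 rises and 1 fall of 23 (14 and 2 adjusted over the list alone, adjusted p = 0.00091, and 0.319 with an estimated correlation). The interferon list did not pass, with 7 rises and 3 falls of 24 (7 and 3 adjusted over the list alone, adjusted p = 0.055, and 0.583 with an estimated correlation). Without uninjured replicate 95 or 96 its adjusted p was 0.0263 or 0.0212.

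Antigen presentation genes went down to a lesser degree. Of 12 MHC class II genes 7 fell, 1 rose and 4 did not pass (8 and 1 adjusted over the list alone, adjusted p = 0.00321, and 0.251 with an estimated correlation). Ciita, the master regulator of these genes, fell from 16573 ± 2454 to 7887 ± 363 (log2 fold change -1.06, SE 0.19, adjusted p = 0.000644), and H2-Ob fell by 2.35. H2-Ab1 went from 121872 ± 12628 to 59891 ± 4751 (-1.02, adjusted p = 0.0217). Its call ended without uninjured replicate 95 (adjusted p = 0.0641) or 96 (0.0538), without injured replicate 5 (0.0596) and with marker means of other kidney cells as covariates (0.0837). Cd74 (-0.65, adjusted p = 0.0623) and H2-Aa (-0.69, adjusted p = 0.147) missed the threshold in the fit of all 15 libraries and passed with only the 6 libraries of both groups (2.39e-05 and 4.51e-05). The fit of all libraries shares its estimate of spread with groups not compared here. Mean deviations of this list from the group mean were 0.28, -0.50 and 0.22 in injured MHCII-negative libraries. In injured MHCII-positive libraries they were -0.02, -0.12 and 0.14.

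Of 61 Wnt pathway genes 29 rose, 4 fell and 28 did not pass (31 and 6 adjusted over the list alone, adjusted p = 0.00164, and 0.236 with an estimated correlation). The receptor genes Fzd1 and Lrp6 rose by 2.98 and 0.76, and Dvl1 fell by 0.78. Of the 61, only 33 had a mean of at least 50 normalized counts over all libraries. Some rises were at low counts, with Wnt9a going from 0 to 7.16, Wnt2 from 0 to 4.14 and Fzd2 from 2.95 to 14.8. Lrp6 in contrast went from 3015 to 5116. Fetal growth genes had 7 rises and 1 fall of 16 (8 and 1 adjusted over the list alone, adjusted p = 0.0168, and 0.236 with an estimated correlation), among them the growth factor gene Mdk at 1.89. Markers of other kidney cells rose beside these. The tubule injury gene Havcr1 had 784 reads in injured against 2 in uninjured libraries, a ratio of 407 (counting interval 112 to 3369), and its call ended with limma-voom (adjusted p = 0.0875). Stroma markers had 9 rises of 11 (9 adjusted over the list alone, adjusted p = 0.000149, and 0.208 with an estimated correlation) and their share of reads went from at most 0.00321% to at least 0.0150%. Nephron epithelium had 6 rises of 22 (6 adjusted over the list alone, adjusted p = 0.0229, and 0.583 with an estimated correlation, but 0.101 without uninjured replicate 95 and 0.128 without injured replicate 4). Endothelium had 5 of 12 (7 adjusted over the list alone, adjusted p = 0.0182, and 0.484 with an estimated correlation, but 0.0565 without injured replicate 4), and nephron progenitor 3 rises and 1 fall of 7 (3 and 1 adjusted over the list alone, adjusted p = 0.3, and 0.583 with an estimated correlation).

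Markers of blood cells fell or did not pass. Of 10 B cell genes 9 fell (9 adjusted over the list alone, adjusted p = 0.00321, and 0.0526 with an estimated correlation), with Igkc at -3.65. Of 13 neutrophil genes 8 fell and 1 rose (8 and 1 adjusted over the list alone, adjusted p = 0.00321, and 0.0526 with an estimated correlation). Of 7 erythroid genes 6 fell (6 adjusted over the list alone, adjusted p = 0.000838, and 0.134 with an estimated correlation). Of 13 dendritic cell genes 4 fell (4 adjusted over the list alone, adjusted p = 0.0357, and 0.141 with an estimated correlation, but 0.0612 without uninjured replicate 96 and 0.0531 without injured replicate 5), with Clec9a at -2.54. Of 14 T and NK cell genes none passed (0 adjusted over the list alone, adjusted p = 0.938, and 0.962 with an estimated correlation). The resident macrophage core had 10 rises and 4 falls of 20 (10 and 4 adjusted over the list alone, adjusted p = 0.0257, and 0.484 with an estimated correlation, but 0.0614 without uninjured replicate 98 and 0.0552 without injured replicate 5). Its tetraspanin genes went apart, with Cd63 rising from 1194 to 3274 normalized counts and Cd81 at -1.09. Among the genes followed throughout were Fn1 (ENSMUSG00000026193, chromosome 1, 71585520 to 71653200), Mrc1 (ENSMUSG00000026712, chromosome 2, 14229392 to 14332057) and H2-Ab1 (ENSMUSG00000073421, chromosome 17, 34263209 to 34269418). In all, 5792 genes were higher and 5012 lower after injury, of 24911 tested, and 5117 changed at least 2-fold (3284 higher, 1833 lower). With the marker means as covariates, 6868 genes passed.

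**Figure D2:**
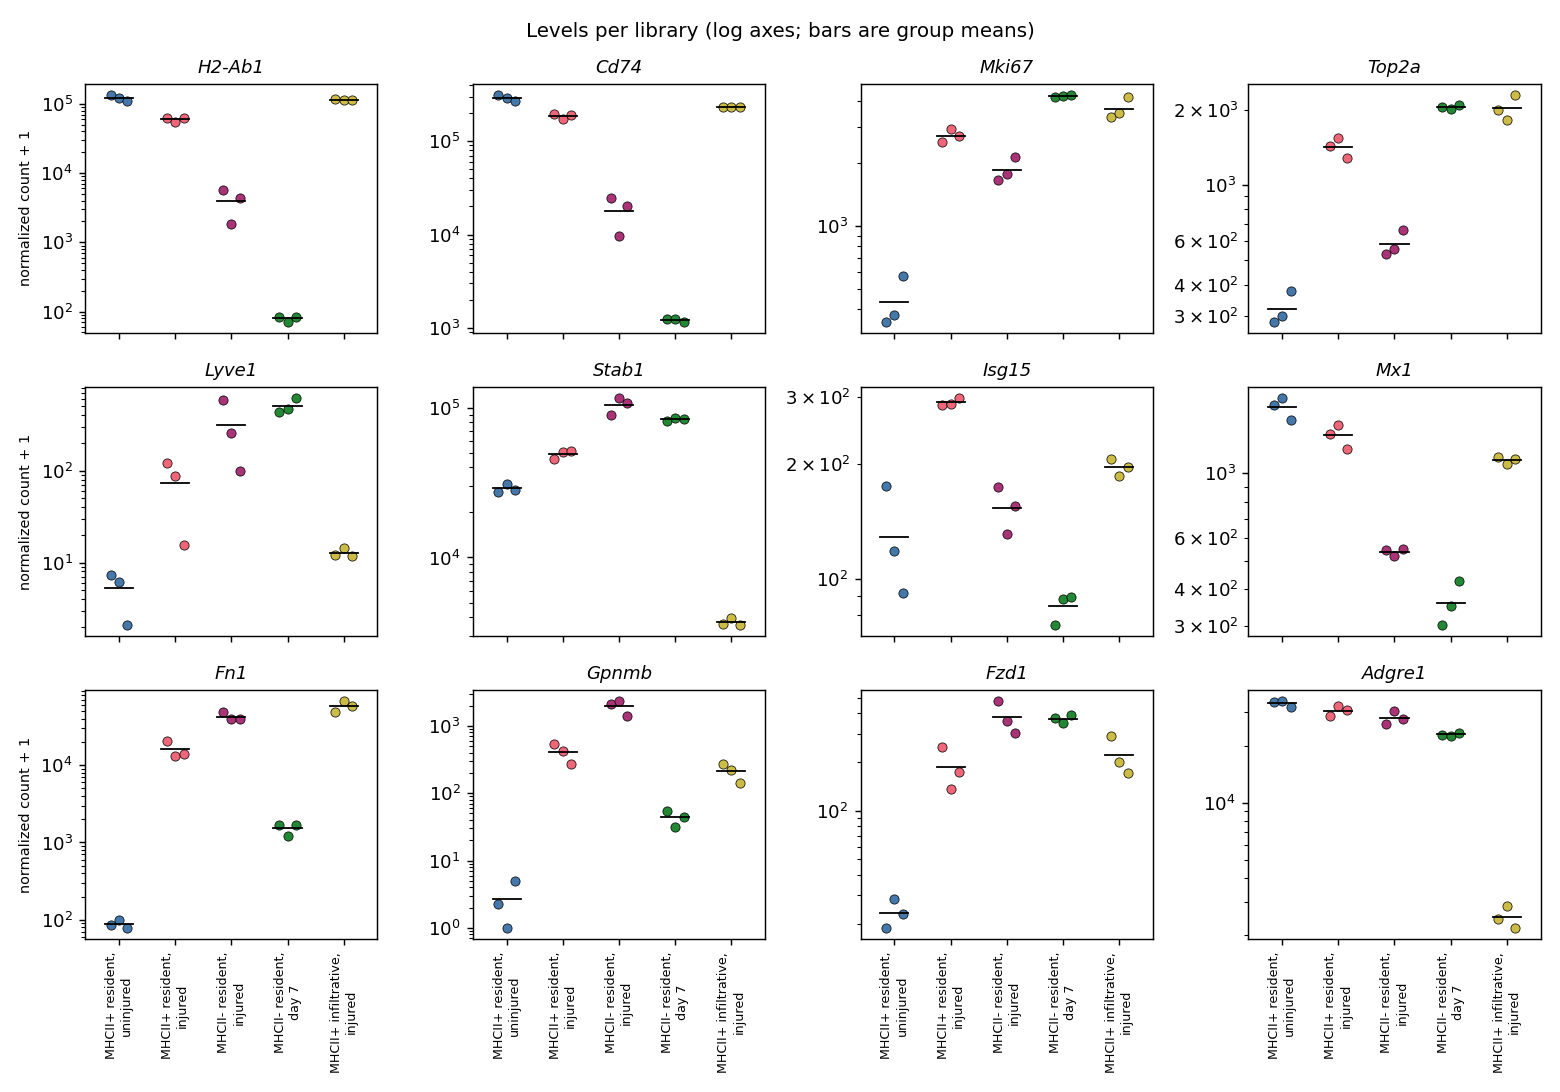
Normalized count plus 1 on a log axis for 12 genes in each of the 15 libraries, by group; points are libraries and bars are group means. H2-Ab1 averaged 121872 in uninjured, 3982 in injured MHCII-negative and 78.5 in day 7 macrophages, and Fn1 averaged 86.8 in uninjured and 42370 in injured MHCII-negative macrophages.

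The next comparison asked what sets resident macrophages of the developing kidney at postnatal day 7 apart from uninjured adult ones; they differ in age and in MHC class II at once. MHC class II genes showed the largest falls: all 12 fell (12 adjusted over the list alone, adjusted p = 8.06e-12, and 0.0538 with an estimated correlation). H2-Eb1 went from 153440 ± 17325 in uninjured adults to 52.1 ± 7.81 at day 7 (n = 3 each; log2 fold change -11.50, SE 0.39, adjusted p = 1.03e-09), and Ciita fell by 8.06. The integrin gene Itgax, which encodes CD11c, fell by 5.87 (SE 0.12, adjusted p = 2.58e-14), and Ccr2 from 5972 ± 440 to 257 ± 28.0. All 24 interferon response genes fell (24 adjusted over the list alone, adjusted p = 2.76e-12, and 0.136 with an estimated correlation), with the antiviral gene Mx1 at -2.23 and Usp18 at -2.57.

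Genes of growth and of the LYVE1 subset were higher at day 7. Of 16 fetal growth genes all rose (16 adjusted over the list alone, adjusted p = 2.64e-07, and 0.0538 with an estimated correlation): Ptn, a growth factor gene, was at least 325-fold higher, and the imprinted gene H19 at least 422-fold higher (379 ± 3.71 against 0 in all 3 adult libraries). With the marker means as covariates, H19 no longer passed (log2 fold change 3.54, adjusted p = 0.243). Of 42 cell cycle genes 39 rose (39 rose and 1 fell adjusted over the list alone, adjusted p = 5.87e-14, and 0.117 with an estimated correlation), with Cenpf at 3.85. In the LYVE1 TIMD4 FOLR2 list 17 of 18 rose (17 adjusted over the list alone, adjusted p = 1.46e-08, and 0.0479 with an estimated correlation). Its scavenger receptor gene Cd163 rose from 172 ± 18.8 to 3061 ± 68.1 (4.16, SE 0.13, adjusted p = 1.48e-13) and Mrc1 by 2.15. Of 61 Wnt genes 46 rose and 2 fell (46 and 3 adjusted over the list alone, adjusted p = 5.27e-06, and 0.138 with an estimated correlation); Fzd1 rose from 22.3 ± 4.80 to 370 ± 20.9 and Lrp6 from 3015 ± 135 to 8522 ± 434. Oxidative phosphorylation had 23 rises of 26 (24 adjusted over the list alone, adjusted p = 3.44e-05, and 0.417 with an estimated correlation). The resident core did not move one way, with 9 rises and 10 falls of 20 (9 and 10 adjusted over the list alone, adjusted p = 0.328).

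Markers of other kidney cells were measured in the day 7 libraries as well. Nephron progenitor markers had 5 rises and 1 fall of 7 (5 and 1 adjusted over the list alone, adjusted p = 0.0802, and 0.46 with an estimated correlation) and nephron epithelium 7 rises and 2 falls of 22 (7 and 2 adjusted over the list alone, adjusted p = 0.294, and 0.828 with an estimated correlation), so neither list passed. Their shares of reads were still higher in every day 7 library than in any uninjured one. Nephron progenitor took at least 0.00525% against at most 0.00131%, and nephron epithelium at least 0.130% against at most 0.0730%. The podocyte gene Nphs1 had 1461 reads against 2, a ratio of 662 (counting interval 183 to 5472). With the marker means as covariates, Nphs1 no longer passed (3.16, adjusted p = 0.109). Wt1, a gene of nephron progenitors and podocytes, had 1804 reads against 3, a ratio of 545 (186 to 2645). Stroma markers all rose, 11 of 11 (11 adjusted over the list alone, adjusted p = 0.000145, and 0.232 with an estimated correlation), from at most 0.00321% to at least 0.0536% of reads. Endothelium had 11 rises and 1 fall of 12 (11 and 1 adjusted over the list alone, adjusted p = 0.0184, and 0.566 with an estimated correlation). Erythroid markers held 0.0118% to 0.0226% of reads at day 7 and at most 0.00177% elsewhere. Xist, the X inactivation RNA of female cells, stood at 23979 and 21446 in day 7 replicates 1 and 2 and at 18.0 in replicate 3, with adults at most at 137. The Y-linked gene Ddx3y stood at 1265, 1215 and 1938 in day 7 replicates 1, 2 and 3, so replicates 1 and 2 held both female and male RNA. In all, 8798 genes were higher and 6193 lower at day 7; 9205 changed at least 2-fold, 6608 of them higher. Without the libraries that hold Xist 10000 passed (5699 higher, 4301 lower), with replicate 3 as the only day 7 library, assumed to vary like the other groups. TMM scaling moves the median of all genes by -0.11 here, and with marker means as covariates 6654 genes passed. The deposited table of the authors has 11718 genes with an adjusted p under 0.05 (7017 higher, 4701 lower), and 11562 of the 14991 genes called here were called there in the same direction.

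The central comparison set MHCII-negative against MHCII-positive resident macrophages, both from injured kidneys; it addresses whether injured MHCII-negative cells lean toward the day 7 state, as the title of the series poses. MHC class II genes fell, as the sort implies: 11 of 12 fell (12 adjusted over the list alone, adjusted p = 5.13e-23, and 0.0101 with an estimated correlation). H2-Ab1 was 3982 ± 1975 in MHCII-negative against 59891 ± 4751 in MHCII-positive macrophages (n = 3 each; log2 fold change -4.06, SE 0.31, adjusted p = 1.02e-05). Interferon response genes fell too, 22 of 24 (24 adjusted over the list alone, adjusted p = 5.13e-23, and 0.0405 with an estimated correlation), with Mx1 from 1347 ± 128 to 538 ± 14.4 (-1.32, SE 0.11, adjusted p = 4.57e-07). The LYVE1 TIMD4 FOLR2 list was higher, with 9 rises and no fall of 18 (14 rises adjusted over the list alone, adjusted p = 2.5e-11, and 0.0101 with an estimated correlation). Cd163 rose from 612 ± 125 to 2010 ± 260 (1.72, SE 0.13, adjusted p = 1.46e-07), and Stab1, the scavenger receptor stabilin, rose by 1.08 (SE 0.08, adjusted p = 1.46e-07). B cell markers and dendritic cell markers fell, 3 of 10 (3 adjusted over the list alone, adjusted p = 0.00122, and 0.0313 with an estimated correlation) and 4 of 13 (6 adjusted over the list alone, adjusted p = 0.0012, and 0.0341 with an estimated correlation), with Ighm at -1.34 and Batf3 at -1.43.

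Cell cycle genes were lower in the MHCII-negative cells, with 23 falls and 1 rise of 42 (31 and 1 adjusted over the list alone, adjusted p = 1.56e-19, and 0.0554 with an estimated correlation). The replication genes Mcm5 and Mcm6 fell by 1.32 and 1.00; the centromere gene Cenpa, at 0.82, lost its call without MHCII-positive replicate 4 (adjusted p = 0.0698) or MHCII-negative replicate 2 (0.0729) or 3 (0.0711). Glycolysis and hypoxia had 9 rises of 22 (15 adjusted over the list alone, adjusted p = 1.86e-07, and 0.188 with an estimated correlation), with the lactate transporter gene Slc16a3 at 1.01. Alternative activation and repair did not pass, with 8 rises and 4 falls of 22 (10 and 5 adjusted over the list alone, adjusted p = 0.199, and 0.464 with an estimated correlation). Its member Arg1 (arginase, 1.98, SE 0.22, adjusted p = 5.95e-05) and Fn1 (1.43, SE 0.19, adjusted p = 0.000449) rose, while Mmp13 fell by 3.50. Of Wnt genes 6 rose and 1 fell of 61 (6 and 1 adjusted over the list alone, adjusted p = 0.0238, and 0.517 with an estimated correlation), and the list's call ended without MHCII-positive replicate 5 (adjusted p = 0.35) or MHCII-negative replicate 1 (0.276). Lrp6 rose from 5116 ± 246 to 9241 ± 1068 (0.85, SE 0.08, adjusted p = 1.77e-06). Infiltrating monocyte genes had 7 rises and 3 falls of 20 (7 and 4 adjusted over the list alone, adjusted p = 0.0352, and 0.627 with an estimated correlation, but 0.141, 0.156 and 0.353 without MHCII-positive replicate 5 or 6 or MHCII-negative replicate 1), with Thbs1 at 1.86 and Ccr2 at -1.11. T and NK cell markers had 1 rise of 14 (4 adjusted over the list alone, adjusted p = 0.00351, and 0.188 with an estimated correlation), and neutrophil markers 1 of 13 (1 adjusted over the list alone, adjusted p = 0.0219, and 0.0647 with an estimated correlation). The latter was the gelatinase gene Mmp9, which macrophages also express, from 151 ± 34.5 to 772 ± 73.6.

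Other lists did not pass in this comparison, including fetal growth genes with 0 rises and 1 fall of 16 (0 and 1 adjusted over the list alone, adjusted p = 0.849) and nephron epithelium with 0 of 22 in either direction (0 adjusted over the list alone, adjusted p = 0.472), tested without a block. Stroma had 2 rises and no fall of 11 (2 adjusted over the list alone, adjusted p = 0.0834, and 0.692 with an estimated correlation). Still, in each of the 3 pairs of libraries matched by shared deviations the MHCII-negative library held the larger share of these markers. Nephron epithelium took 0.281%, 0.0598% and 0.115% of reads against 0.192%, 0.0564% and 0.0940%, and stroma 0.0727%, 0.0262% and 0.0199% against 0.0420%, 0.0194% and 0.0150%. The resident core had 7 rises and 5 falls of 20 (9 and 6 adjusted over the list alone, adjusted p = 0.997), and its median and mean differ in sign, as they or the test do for inflammatory cytokine and endothelium lists. Adgre1 stood at 28109 ± 2256 against 30567 ± 1686 (adjusted p = 0.441). In all, 987 genes were higher and 1297 lower; 676 changed at least 2-fold (243 higher, 433 lower). Without MHCII-positive replicate 5, 1490 genes passed, and with only the 6 libraries of both groups 1478. With the injured libraries matched by their shared deviations as a block, a pairing derived from these data and not given by the labels, 4594 passed (2509 higher, 2085 lower).

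Genes that set day 7 apart from uninjured macrophages by at least 2-fold were then followed between the injured groups, which share no library with that contrast. Both contrasts set an MHCII-negative against an MHCII-positive sort, so a difference tied to MHCII status cannot be told apart from a lean toward day 7. Stroma markers rose at day 7 and held a larger share of reads in the MHCII-negative library of each matched pair. RNA of other kidney cells may therefore add to the lean. The 2597 genes lower at day 7 leaned down in MHCII-negative macrophages, with a median log2 fold change of -0.32; 689 fell and 26 rose (adjusted over all genes), and camera gave p = 4.95e-29, or 5.43e-05 with an estimated correlation. H2-Eb1, Mmp13, the integrin gene Itga8 (-3.21) and the adaptor gene Grap2 (-3.59) were among them. The 6608 genes higher at day 7 leaned up, with a median of 0.28; 363 rose and 124 fell, and camera gave p = 1.79e-06, or p = 0.0863 with an estimated correlation. The median of genes higher at day 7 moved with the libraries left out: it was 0.11 without MHCII-negative replicate 1, 0.13 without MHCII-positive replicate 5 and 0.45 without MHCII-negative replicate 2, past the camera threshold each time at the preset correlation. These libraries deviate in matched sets, and without the first set (69, 4 and 1) the median was 0.22. Coagulation factor gene F5 (3.06) and Cd163 were among the genes higher at day 7. Leaving out genes with at most 3 reads in a group, 151 and 1150 of them, the medians were -0.31 and 0.28. Leaving out the MHC class II list instead, they were -0.32 and 0.28. Fitting marker means of other kidney cells as covariates gave -0.32 and 0.21 (camera p = 3.37e-25 and 0.000153 at the preset correlation). Across genes the fold changes correlated at r = 0.369 (Spearman's rho 0.375); genes are not independent replicates. Of genes past the threshold in both contrasts, 667 were higher in both (349 if calls were independent), 992 lower in both (322) and 309 went opposite ways (703).

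**Figure D3:**
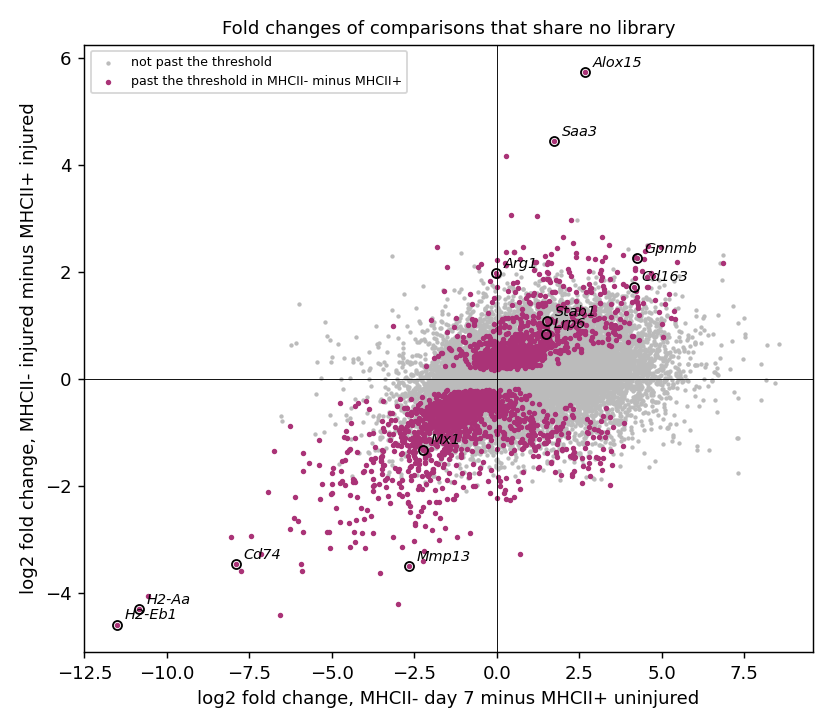
Log2 fold change of day 7 against uninjured macrophages on the x axis and of injured MHCII-negative against injured MHCII-positive macrophages on the y axis; each point is 1 of 24911 tested genes, coloured where it passed the threshold on the y axis. Of coloured genes that also passed on the x axis, 992 were lower in both, 667 higher in both and 309 opposite.

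Set against uninjured macrophages, the same genes moved further in both injured groups. In MHCII-positive macrophages the genes higher at day 7 had a median log2 fold change of 1.03 (1.12 without genes at the read floor) with 2870 rises and 40 falls, and those lower at day 7 had -0.96 (-0.94) with 85 rises and 1754 falls. In MHCII-negative macrophages the medians were 1.32 (1.41) and -1.28 (-1.25), with 3546 rises and 45 falls, and 81 rises and 2051 falls. Genes higher in both contrasts numbered 4178 for MHCII-positive (2046 if independent) and 5072 for MHCII-negative cells (2526); genes lower in both numbered 3684 (1246) and 4205 (1455). All these contrasts share the 3 uninjured libraries. Simulated unchanged groups against those libraries gave a correlation of 0.517 by sharing alone (highest 0.538 of 50), beside 0.682 and 0.723 observed, and a covariance of 0.0799 (highest 0.0848), beside 1.20 and 1.54. The 3 controls cannot be divided into parts of at least 2 libraries each, so the contrasts could not be given separate controls. Random spread of the shared controls gave a simulated covariance of at most 0.0848, beside 1.20 and 1.54 observed. Across the tested genes, these values argue against that spread as the sole source of the overlap. These contrasts also cross the title styles in the same direction, which the simulation leaves out, so a batch shift cannot be told apart from the overlap there.

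Injured MHCII-negative macrophages were also set against uninjured ones, a comparison in which injury and MHC class II differ together. Fn1 rose from 86.8 ± 10.1 to 42370 ± 5752 (n = 3 each; log2 fold change 8.91, SE 0.19, adjusted p = 3.81e-12) and Gpnmb from 1.73 ± 1.99 to 1936 ± 477 (9.73, SE 0.49, adjusted p = 4.82e-09). The deiodinase gene Dio2 had 847 reads against 1, a ratio of 1064 (counting interval 190 to 42067). H2-Ab1 fell by 5.08 (SE 0.31, adjusted p = 1.53e-07) and Ptchd1 from 1212 ± 230 to 7.97 ± 5.52. LYVE1 subset genes rose, 17 of 18 (17 adjusted over the list alone, adjusted p = 3.79e-09, and 0.0299 with an estimated correlation), with Cd163 at 3.54, and 9 of 10 B cell markers fell (9 adjusted over the list alone, adjusted p = 0.000284, and 0.0316 with an estimated correlation). MHC class II had 11 falls and 1 rise of 12 (11 and 1 adjusted over the list alone, adjusted p = 1.98e-08, and 0.0961 with an estimated correlation), the rise being the protease gene Ctss at 0.22, which lost its call with the marker means as covariates (adjusted p = 0.0692) and in edgeR with TMM (0.0583) or upper quartile factors (0.0666). Interferon genes had 16 falls and 1 rise of 24 (16 and 1 adjusted over the list alone, adjusted p = 0.0002, and 0.307 with an estimated correlation). Wnt genes had 35 rises and 3 falls of 61 (35 and 3 adjusted over the list alone, adjusted p = 0.000251, and 0.226 with an estimated correlation), beside 9 rises of 11 stroma markers (9 adjusted over the list alone, adjusted p = 0.000251, and 0.232 with an estimated correlation). Cell cycle genes had 27 rises and 3 falls of 42 (28 and 3 adjusted over the list alone, adjusted p = 5.97e-05, and 0.279 with an estimated correlation). In all, 7151 genes were higher and 5853 lower; 7202 changed at least 2-fold (4410 higher, 2792 lower), and 8051 passed with the marker means as covariates.

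How far injured MHCII-negative macrophages remained from day 7 ones was asked directly. Thbs1 was 80333 ± 7070 in injured against 1156 ± 43.5 in day 7 macrophages (n = 3 each; log2 fold change 6.11, SE 0.18, adjusted p = 7.04e-11), and Ccr2 was 8413 ± 1359 against 257 ± 28.0 (5.02, SE 0.13, adjusted p = 1.14e-12). The guanine deaminase gene Gda was higher by 9.39 (SE 0.24, adjusted p = 1.65e-11) and the activating receptor gene Trem1 by 6.92. The fetal growth genes Igf2 and Igf2bp3 were lower, by log2 fold changes of -5.70 and -2.82, as 14 of 16 in that list were (15 adjusted over the list alone, adjusted p = 1.56e-08, and 0.0733 with an estimated correlation). Nephron progenitor markers took 0.00525% to 0.00671% of reads at day 7 and 0.000837% to 0.00274% in injured libraries. Shares of stroma, endothelium and nephron epithelium markers overlapped. RNA of other kidney cells may therefore add to the falls in the fetal growth list. Cell cycle genes were lower in 38 of 42 (38 adjusted over the list alone, adjusted p = 1.36e-14, and 0.0981 with an estimated correlation), with Top2a at -1.82 (SE 0.11, adjusted p = 2.03e-09). MHC class II was higher in 10 of 12 (10 adjusted over the list alone, adjusted p = 1.56e-08, and 0.0981 with an estimated correlation), with H2-Ab1 at 3982 ± 1975 against 78.5 ± 7.09. Interferon genes were higher in 22 of 24 (22 adjusted over the list alone, adjusted p = 1.66e-11, and 0.101 with an estimated correlation), with Usp18 at 1.64. Infiltrating monocyte genes were higher in 15 of 20 and lower in 2 (15 and 2 adjusted over the list alone, adjusted p = 4.17e-09, and 0.0981 with an estimated correlation). The LYVE1 subset list did not lean, with 6 rises and 7 falls of 18 (6 and 7 adjusted over the list alone, adjusted p = 0.638): Timd4, the phosphatidylserine receptor, fell by 3.68 (SE 0.37, adjusted p = 6.46e-07), while Clec4n rose by 1.03.

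In the same comparison the resident core rose in 17 of 20 and fell in 2 (17 and 2 adjusted over the list alone, adjusted p = 2.32e-07, and 0.128 with an estimated correlation), while its member Cx3cr1 fell from 26572 to 9716 (adjusted p = 0.000122). Glycolysis and hypoxia rose in 16 of 22 and fell in 2 (20 and 2 adjusted over the list alone, adjusted p = 3.31e-09, and 0.101 with an estimated correlation), with the glucose transporter gene Slc2a1 at 2.22. Of 7 erythroid genes 6 fell (7 adjusted over the list alone, adjusted p = 4.49e-06, and 0.0733 with an estimated correlation); Hba-a2 was at least 103-fold lower, though reads of the paired haemoglobin genes cannot be assigned with certainty. Wnt genes fell in 17 and rose in 5 of 61 (17 and 5 adjusted over the list alone, adjusted p = 0.045, and 0.476 with an estimated correlation, but 0.059 without day 7 replicate 3, 0.119 and 0.0502 without injured replicate 2 or 3). In all, 4691 genes were higher and 5297 lower than at day 7; 5020 changed at least 2-fold (1437 higher, 3583 lower). The balance turned with TMM factors in limma (5249 higher, 4750 lower). Without the day 7 libraries that hold Xist 4475 passed (2633 higher, 1842 lower), with replicate 3 as the only day 7 library, assumed to vary like the other groups, and with the marker means as covariates 5335. Label numbers 1 to 3 stand in both groups, and with number as a block 9115 passed, yet deviations of libraries with the same number correlated between -0.08 and 0.00, so the numbers do not pair the libraries.

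The last comparison asked how infiltrative phagocytes differ from MHCII-positive resident macrophages of injured kidneys. Every gene of the resident core fell, 20 of 20 (20 adjusted over the list alone, adjusted p = 1.18e-21, and 0.0281 with an estimated correlation): Adgre1, which encodes F4/80, was 2497 ± 337 against 30567 ± 1686 (n = 3 each; log2 fold change -3.62, SE 0.08, adjusted p = 4.22e-15), and the complement gene C1qa was 3372 ± 409 against 29214 ± 547 (-3.12, SE 0.08, adjusted p = 3.13e-14). Dendritic cell markers rose in 11 of 13 and fell in 1 (12 and 1 adjusted over the list alone, adjusted p = 2.25e-07, and 0.00877 with an estimated correlation). Zbtb46, a transcription factor of classical dendritic cells, rose from 112 ± 27.9 to 3264 ± 93.8, Cd209a from 58.0 ± 49.4 to 14286 ± 1810 and the migration receptor gene Ccr7 from 19.9 ± 7.09 to 4112 ± 220, while Irf8 fell by 0.44. These markers took 0.203% to 0.222% of reads in infiltrative phagocytes and 0.0377% to 0.0414% in resident macrophages. The chemokine genes Ccl17 and Ccl22 rose by 7.08 and 7.07, and Ccl8 and Ccl12 fell by 6.83 and 5.01.

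LYVE1 subset genes fell in 12 of 18 and rose in 2 (14 and 2 adjusted over the list alone, adjusted p = 2.25e-07, and 0.0281 with an estimated correlation), with Stab1 at -3.72 and Igf1 at -4.82. Infiltrating monocyte genes rose in 16 of 20 (16 adjusted over the list alone, adjusted p = 1.55e-08, and 0.0974 with an estimated correlation), though Ly6c2 itself stood at 37.1 ± 2.57 against 20.2 ± 10.2 (adjusted p = 0.184). Glycolysis and hypoxia rose in 20 of 22 (20 adjusted over the list alone, adjusted p = 1.76e-10, and 0.0974 with an estimated correlation), with Pfkp at 3.00. MHC class II rose in 8 of 12 and fell in 1 (8 and 1 adjusted over the list alone, adjusted p = 0.000149, and 0.219 with an estimated correlation); H2-DMb2 rose by 4.87, and Cd74 stood at 231288 ± 1674 against 184990.0 ± 12255 (adjusted p = 0.372, and 0.000948 with only the 6 libraries of both groups). Interferon genes fell in 21 of 24 (22 adjusted over the list alone, adjusted p = 1.71e-10, and 0.145 with an estimated correlation) and complement genes in 10 of 16 with 2 rises (10 and 2 adjusted over the list alone, adjusted p = 7.65e-05, and 0.071 with an estimated correlation). Cell cycle genes rose in 25 of 42 and fell in 1 (28 and 1 adjusted over the list alone, adjusted p = 2.82e-05, and 0.365 with an estimated correlation), with Tk1 at 2.14. Wnt genes rose in 9 and fell in 11 of 61 (9 and 11 adjusted over the list alone, adjusted p = 0.337), although Wnt11 rose by 6.19, from 11.1 ± 2.05 to 882 ± 159. In all, 5020 genes were higher and 4254 lower; 4105 changed at least 2-fold (2031 higher, 2074 lower). The balance turned with TMM factors in limma (4356 higher, 4688 lower).

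**Figure D4:**
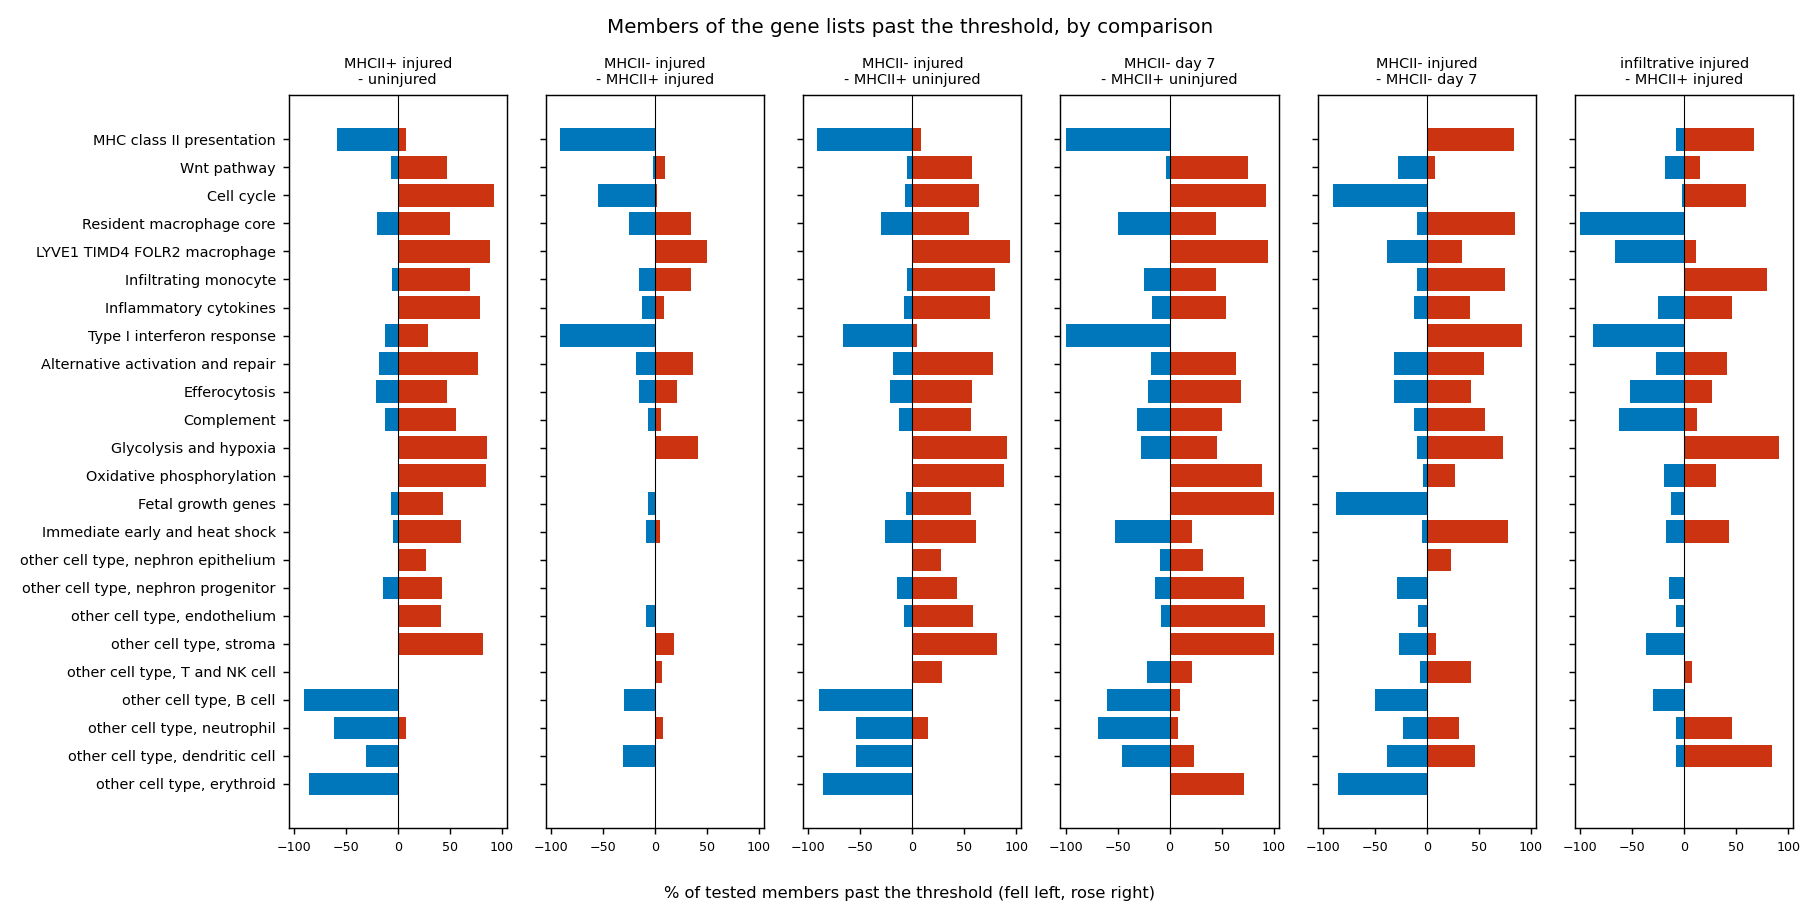
Percentage of tested members of each gene list that rose or fell past the threshold, for the 6 comparisons. All 20 resident core genes fell in infiltrative phagocytes against resident macrophages, and all 24 interferon genes fell at day 7 against uninjured macrophages.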

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

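The marker covariates, the matched and Xist settings, the removal of libraries high in nephron markers, and TMM factors in limma and edgeR were chosen after the data were seen, and the other settings before. Of 521 values of named genes, 513 kept their direction and side of the threshold with DESeq2, 507 with limma-voom, 516 with TMM factors in limma and 463 with marker means of other kidney cells as covariates. When 1 library was left out in turn, 3013 of 3126 did so, 110 lost and 3 gained a call. Most of these genes were named for large folds without overlap or for small adjusted p in the same data. Their stability therefore cannot speak for the other calls. Of 144 list results 90 were past the threshold, of which 13 kept their call with an estimated correlation and 77 lost it, so list p-values depend on that choice. A gene counted as reversed only where a value was past the threshold. Gene counts were lower where a fold of at least 2 was required, by the construction of that setting: 5117 (injured MHCII-positive against uninjured), 676 (MHCII-negative against MHCII-positive after injury), 7202 (injured MHCII-negative against uninjured), 9205 (day 7 against uninjured), 5020 (injured MHCII-negative against day 7) and 4105 (infiltrative against resident). With marker means as covariates, counts were 6868 in the first, 8051 in the third, 6654 in the fourth and 5335 in the fifth, while the second had 3058 (1535 higher, 1523 lower) and the sixth 8878, and the cause was not tested. MHCII-negative against MHCII-positive gave 1478 genes with only the 6 libraries of both groups and 4594 with libraries matched by shared deviations as a block; injured MHCII-negative against day 7 gave 4475 without the day 7 libraries that hold Xist, where only 1 day 7 library was left and was assumed to vary like the other groups. Leaving out 1 library gave 8966 to 10174, 1490 to 2217, 11679 to 12578, 13542 to 14009, 8115 to 9638 and 8007 to 8885 genes in the same order; the 1490 were without injured MHCII-positive replicate 5. For genes higher at day 7 (median 0.28 between the injured groups) p was 0.0863 with an estimated correlation, against 1.79e-06. Without 1 library that median ran from 0.11 (without MHCII-negative replicate 1) to 0.45 (without MHCII-negative replicate 2). Which direction held more genes turned with some settings: MHCII-negative against MHCII-positive had 2509 higher and 2085 lower with the matched block, infiltrative against resident had 4123 higher and 4789 lower with upper quartile factors and 4291 and 4521 with TMM factors in edgeR, injured MHCII-negative against day 7 had 5329 and 4469 with TMM factors in edgeR 4682 and 4431 with DESeq2, 4507 and 4277 at a pseudocount of 0.1, 4584 and 4106 with the stricter filter and 2697 and 2638 with the covariates, and injured MHCII-positive against uninjured had 5310 and 5570 with upper quartile factors. For efferocytosis in injured MHCII-negative against day 7 macrophages, camera, which compares with other genes, pointed up (adjusted p = 0.939) and directional fry, which compares with no change, pointed down (adjusted p = 0.00406), as the list's median (-0.02) did. With the covariates, 2 genes of injured MHCII-negative macrophages changed sign: Ddx58 was -0.0020 (adjusted p = 0.992) and Tk1 0.0695 (adjusted p = 0.779) against uninjured macrophages; the cause was not tested. Depth of 13482981 to 34295930 reads limits genes near 0 counts, for which only bounds or counting intervals are given.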

Other observations

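Tests of matching by label number and of Wnt genes with covariates were chosen after the results were seen. The tests of other splits were chosen before. Those of admixture and peritoneal cells were chosen before their own results, for patterns first seen in these data. Some named genes not described above also differed between the groups. F10, which encodes coagulation factor X, had 990 reads in injured MHCII-negative against 1 in uninjured macrophages, a ratio of 1243 (counting interval 223 to 49161), and the integrin gene Itgam was higher by 2.70 in injured MHCII-positive than in uninjured macrophages. The macrophage elastase gene Mmp12 and the receptor gene Slamf7 were lower at day 7 than in uninjured macrophages, at -6.27 and -6.93. The chemokine gene Ccl8 and the lipocalin gene Lcn2 were higher by 6.95 and 6.35 in injured MHCII-negative than in day 7 macrophages. In infiltrative phagocytes the transporter gene Slco2b1 and the adhesion gene Vcam1 were lower than in resident macrophages, at -5.91 and -5.08.

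The libraries of the 3 injured groups deviated from their group means in matched sets. The matching by ascending label number (69 with 4 and 1, 70 with 5 and 2, 73 with 6 and 3) ranked 1 of 36 by mean correlation (0.613, next best 0.396) over 13203 genes. As this matching was chosen after the results were seen, its rank cannot decide on chance matching of replicates. The first set was high in Postn, Dcn, Col1a1 and Havcr1. With the trend of nephron, stroma and endothelium markers removed, the lowest correlation of the 9 matched pairs was -0.671, the outcome predicted for varying admixture alone. The highest was 0.459. The markers removed were high in all 3 libraries of the first set, so removing their trend also removes whatever else that set shares. The test therefore cannot tell varying admixture of other kidney cells from another shared source in the first set. Only pairs among 69, 4 and 1 turned negative, while those among 70, 5 and 2 kept 0.11 to 0.388 and those among 73, 6 and 3 kept 0.333 to 0.459. Cells sorted from the same animal or on the same day remain open and were not tested, as the labels give neither.

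Prg4, Alox15, Saa3 and Cxcl13 were high in injured MHCII-negative replicates 1 and 2: Prg4 at 333, 181 and 47.0 and Alox15 at 571, 311 and 7.24 in replicates 1, 2 and 3, Saa3 at 780.0, 524 and 47.9, and Cxcl13 at 109, 34.2 and 0.904. These are also the 4 genes in which the deposited mean differs from the plain mean of the libraries. For admixed large peritoneal macrophages 5 of 8 markers lay in the order of replicate 1 above 2 above 3, the outcome predicted for that admixture. The mean deviations of stroma (1.02, -0.32, -0.70) and endothelium markers (1.06, -0.40, -0.66) lay in the same order, however, so the order does not single out a source. Of the 8, only Serpinb2 (159, 65.8 and 9.95) stood above the other groups' highest library (20.4). For admixed mesothelium 1 of 5 detected markers lay in that order, and 2 (Msln at 11.7 against 11.2 and Krt19 at 140.4 against 126.6) stood above the other groups' highest library in replicate 1, which leaves it open, as is a response of the macrophages themselves, which was not tested.

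Wnt list members rose along with markers of other kidney cells against uninjured macrophages, in both injured resident groups and at day 7. Members were followed with the covariates in 2 of these contrasts, those of injured MHCII-positive and day 7 macrophages. With marker means as covariates, 10 of 29 members that rose in injured MHCII-positive macrophages stayed past the threshold, their median log2 fold change going from 2.33 to 1.04 while the median SE went from 0.50 to 0.64; of all genes that rose there, 54.7% stayed, against 34.5% of the members. At day 7, 18 of 46 stayed, with the median going from 2.60 to 1.59 and the SE from 0.51 to 0.98, a share of 39.1% beside 38.2% of all genes that rose, so the list lost no more calls there than other genes. Genes that rose at day 7 include markers of other kidney cells. The like share therefore does not show that Wnt members were free of RNA from those cells. Within each injured group the mean Wnt deviations also followed those of nephron epithelium, with 0.25, -0.27 and 0.02 beside 0.87, -0.81 and -0.07 in MHCII-positive, 0.28, -0.29 and 0.01 beside 1.20, -1.02 and -0.17 in MHCII-negative and 0.15, -0.17 and 0.01 beside 0.95, -1.07 and 0.12 in infiltrative libraries. In the resident groups glycolysis and hypoxia genes had the same order, with 0.20, -0.19 and -0.01 in MHCII-positive and 0.19, -0.16 and -0.03 in MHCII-negative libraries. Infiltrative libraries did not follow it (-0.06, -0.02 and 0.08). In the resident groups the order is thus not particular to Wnt genes and does not single out a source. RNA of other kidney cells could account for part of the rise after injury and at day 7. Its share of the differences between groups cannot be told apart from Wnt expression by macrophages, since the markers differ between the groups as well. Fzd1 and Lrp6 stayed in both contrasts.

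For each comparison the 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Every other split mixes libraries of both groups, so a real difference enters the spread and lowers the calls. The counts of the other splits are therefore no reference for what chance would give. The real split was the only 1 of the 10 with as many genes: 10804 in injured MHCII-positive against uninjured, 13004 in injured MHCII-negative against uninjured, 14991 at day 7 against uninjured, 9988 in injured MHCII-negative against day 7 and 9274 in infiltrative against resident, each beside 0 as the highest other split. It was 2284 in MHCII-negative against MHCII-positive after injury, beside 1 as the highest other.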
